A study of Homo sapiens with 58 samples.

How the data were processed

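RNA was measured in 50 libraries of the ASC52telo line, taken before differentiation and on days 3, 7, 10 and 14 of adipogenic differentiation with DMSO, rosiglitazone or tributyltin. Per the labels' protocols, cells were differentiated with the StemXVivo adipogenic supplement, RNA was extracted with a Qiagen RNeasy kit, and libraries were made with a stranded KAPA kit and sequenced at the New York Genome Center. The doses of both compounds are not given in the sources used here. Nothing in the labels says that the replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

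The deposited values are whole-number read counts per gene, not normalised, per the file headers. The headers name featureCounts 1.4.3-p1 with the reverse-strand setting and the GENCODE 25 gene models on GRCh38. Trim Galore 0.6.5, STAR 2.5.2a, FastQC, Bowtie2 and Picard are named in the submitters' processing notes, without their order. The counting command in the headers has no option for read pairs, so each mate of a pair would count as a read. Even values made up 54.99 to 60.55% of the counts from 1 to 20 in each library. Counts are therefore reads and not molecules, and the floors given for genes with no reads cover counting error only. Genes with near-identical copies, such as those of the actin, tubulin, metallothionein and serum amyloid families, and genes that overlap on the same strand can share or lose reads in such counting, and their values are less certain.

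The files hold 58037 gene identifiers, of which 57433 were named from the gene name table for human genes and 604 were not. A further 1190 shared their name with another identifier and were kept under the identifier. Gene coordinates are those of the count files, on GRCh38. In all, 17655 genes had no read in any library. Total counts ran from 37.3 to 205.4 M reads per library. The labels list 58 samples, of which 8 are repeat runs. Each library had a single column of counts, and a fit on first runs alone was not run.

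Each library was placed by its title, which gives the day, the treatment and the replicate number. For 10 libraries the tags for time and treatment name another group than the title. They are DMSO day 7 replicate 1, TBT day 7 replicates 3 and 4, DMSO day 14 replicate 3, and DMSO replicates 2 and 3, ROSI replicates 2 and 3 and TBT replicates 3 and 4 of day 10. The titles were followed for them, and fits without these libraries and with the groups of the tags were made as alternatives. The groups of the tags also hold AA and AO as 1 group and AET within TBT day 14, since their tags are the same. As a check, each of the 10 was correlated in log2 CPM with the libraries with agreeing labels in the group of its title and of its tags. At day 10 the title's group held 1 such library for DMSO and ROSI replicates 2 and 3. The tags' group held 1 for DMSO replicates 2 and 3 and TBT replicates 3 and 4. By mean r, 9 of the 10 lay closer to the title's group, and DMSO day 14 replicate 3 to the tags' (0.9895 against 0.9894). A score was taken from the 50 genes each way that moved most with TBT in the libraries of days 3 and 14 with agreeing labels. It lay between 1.38 and 2.91 in the 15 TBT libraries and between -1.92 and -0.46 in the 27 DMSO and ROSI libraries of days 3 to 14. For the libraries that set the score this separation is built in. The 6 day 0 libraries lay between 1.62 and 1.95, so the score does not mark TBT alone. For 6 of the 10 the title and the tags fall on the same side of this score, which decides nothing. Of the other 4, TBT day 10 replicates 3 and 4 were at 1.62 and 1.44 and ROSI day 10 replicates 2 and 3 at -1.39 and -1.53, on the side of their titles. The 61 pairs of replicates differed by a chi-square of 3.49 to 239.83 per degree of freedom. Mates counted as separate reads raise this value by themselves, so the lowest values do not rule out technical repeats, and no libraries were merged.

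The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3), two-sided, with TMM scaling, the default low-count filter by group, 1 coefficient per group and all 50 libraries in 1 fit. It tested 22905 genes, with a common dispersion of 0.01205, which is a biological coefficient of variation of 11%. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. The 20 comparisons were TBT and ROSI against DMSO and TBT against ROSI at each of the 4 days, DMSO at each day against day 0 (the mean of the AA and AO coefficients), AET against TBT day 14, AA against AO, and the change of the TBT and the ROSI effect from day 3 to day 14. Levels are TMM-scaled CPM. A fold against a group with no reads was computed against a floor of 3 counts over the group's libraries.

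There were 33 gene lists with 500 measured genes, written from textbook knowledge: adipocyte, early adipogenic regulators, PPAR targets, LXR targets, retinoic acid targets, lipogenesis, cholesterol synthesis, thermogenic, oxidative phosphorylation, actin cytoskeleton, tubulin and microtubule, intermediate filament and lamina, focal adhesion and integrin, YAP TEAD targets, collagen and matrix, proliferation, p53 targets, metallothionein, oxidative stress, unfolded protein and integrated stress, heat shock, inflammation, interferon, glucocorticoid response, autophagy and lysosome, mesenchymal stem cell surface, osteoblast, chondrocyte, skeletal muscle, endothelial, blood and macrophage, epithelial, and nervous and glial. They were tested with camera of limma 3.58.1, with the preset correlation of 0.01 and with a correlation estimated per list, and with fry, on log2 CPM with a prior count of 2, adjusted over the lists within a comparison. Camera asks whether a list moved against all other genes, and fry whether its genes moved on balance to 1 side. A list was treated as called only where camera passed with both correlations. Members were also adjusted over the list alone, and where a bracket gives bare counts before a p, these are the counts adjusted over the list alone and the adjusted p with an estimated correlation. The preset test, the mean and the median differed in sign in AA against AO for PPAR targets and in the TBT change from day 3 to 14 for retinoic acid targets, and neither is called.

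The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The text may name a panel of 18 genes (PPARG, CEBPA, FABP4, ADIPOQ, PLIN1, LPL, CD36, ANGPTL4, PDK4, ABCA1, SCD, ACTA2, TAGLN, TUBB6, COL1A1, MKI67, MT2A and HMOX1) in any comparison. For each list and comparison it may name the up to 4 members with the smallest adjusted p under 0.05, or the most abundant member where none passed. For each treatment and differentiation comparison it may name the 5 genes with the highest and the 5 with the lowest log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. TERT is named as a check of the cell line.

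The gene counts, the named genes and the lists were computed again in the comparisons each alternative bears on: with RLE size factors, without the low-count filter, with DESeq2 1.42.0, with the replicate number as a block, with the flow cell as a term, on the libraries of the compared groups alone, without the contradicted libraries, with the groups of the tags, with AET pooled into TBT day 14, with AA or AO alone as day 0, and leaving out each library in turn. List tests were not run with DESeq2. Added after the data were seen were the share of reads on long noncoding gene types as a term, and the libraries of the most common flow cell alone. The former was fitted for TBT and ROSI against DMSO, and the latter in the comparisons that kept enough libraries. Other splits of the compared libraries into groups of the same sizes, at most 100 per comparison, were fitted to count how many genes they call.

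The scripts were tested on simulated counts drawn for the real genes, with 200 genes changed. For TBT against DMSO at day 7 (21893 genes), 86.7% of genes changed 1.5-fold, 94.5% of those changed 2-fold and 100% of those changed 4-fold were called, and 2.6% of the calls were false. For ROSI against DMSO at day 10 (21910 genes) the shares were 81.9%, 87.3% and 100%, with 4.3% false. For TBT against DMSO at day 14 (21931 genes) they were 77.1%, 87.3% and 100%, with 3.3% false. None of the 50 unchanged lists was called with the preset correlation in any of the 3. Genes were drawn independently in these simulations, so that result does not bear on lists of correlated genes. The changed genes were not taken from those of lowest mean CPM, to which the shares of genes called do not apply. The correlation of TBT and ROSI fold changes with no effect was taken from 20 simulations a day, in which all 3 groups were drawn from the DMSO means; a first version drew the treated groups from means that left out the shared error of the DMSO libraries, and was corrected after its covariance was seen. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.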

Results

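Gene expression was measured by RNA sequencing in ASC52telo cells, a line of human mesenchymal stem cells from adipose tissue made immortal with telomerase. The cells were taken before differentiation (day 0) and on days 3, 7, 10 and 14 of adipogenic differentiation with the vehicle DMSO, with rosiglitazone (ROSI) or with tributyltin (TBT). TBT is an organotin compound known to bind the nuclear receptors PPARG and RXR, and ROSI is a thiazolidinedione drug that activates PPARG. DMSO libraries numbered 3, 4, 3 and 3 at days 3, 7, 10 and 14. ROSI libraries numbered 4, 4, 3 and 3, and TBT libraries numbered 4, 4, 4 and 3. At day 0 there were 6 libraries, 3 with titles beginning AA and 3 with titles beginning AO. A further 2 libraries with titles beginning AET carried the tags of TBT day 14 and were kept as a group of their own. What these letters stand for, and the doses, are not given in the sources used here.

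The 50 libraries held 37.3 to 205.4 M counted reads, with a median of 65.0 M. The DMSO libraries held 68.1 to 205.4 M at day 3, 53.3 to 70.2 M at day 7, 53 to 137.1 M at day 10 and 61.5 to 66.9 M at day 14. For ROSI the ranges were 57.4 to 74.5, 66.8 to 124.5, 51.0 to 60.8 and 56.8 to 75.4 M. For TBT they were 42.2 to 63.7, 57.4 to 130.8, 57.2 to 68.9 and 42.3 to 68.9 M. The AA libraries held 66.1 to 76.0 M, the AO libraries 37.3 to 65.8 M and the AET libraries 45.5 to 68.1 M. Below, a level is a mean of TMM-scaled CPM ± SD over the libraries of a group, and a log2 fold change is given ± SE.

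The telomerase gene TERT, the transgene of this line, lay between 717.8 and 1871 CPM in all 50 libraries. The title, which set the group, and the tags of 10 libraries differed. By correlation of log2 CPM, 9 of them lay closer to the title's group and 1 to the tags', at day 10 in part by r with 1 library. The first principal component, with 28.7% of the variance, placed the day 0 libraries between -150.4 and -131.2 and DMSO day 14 between 40.7 and 50.6. The third, with 8.3%, placed TBT day 14 between -56.4 and -46.2, against -0.7 to 1 for DMSO day 14. TBT day 14 replicate 3 lay near the AET libraries, at -13.6 on the first component against -21.6 to -17.9.

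**Figure D1:**
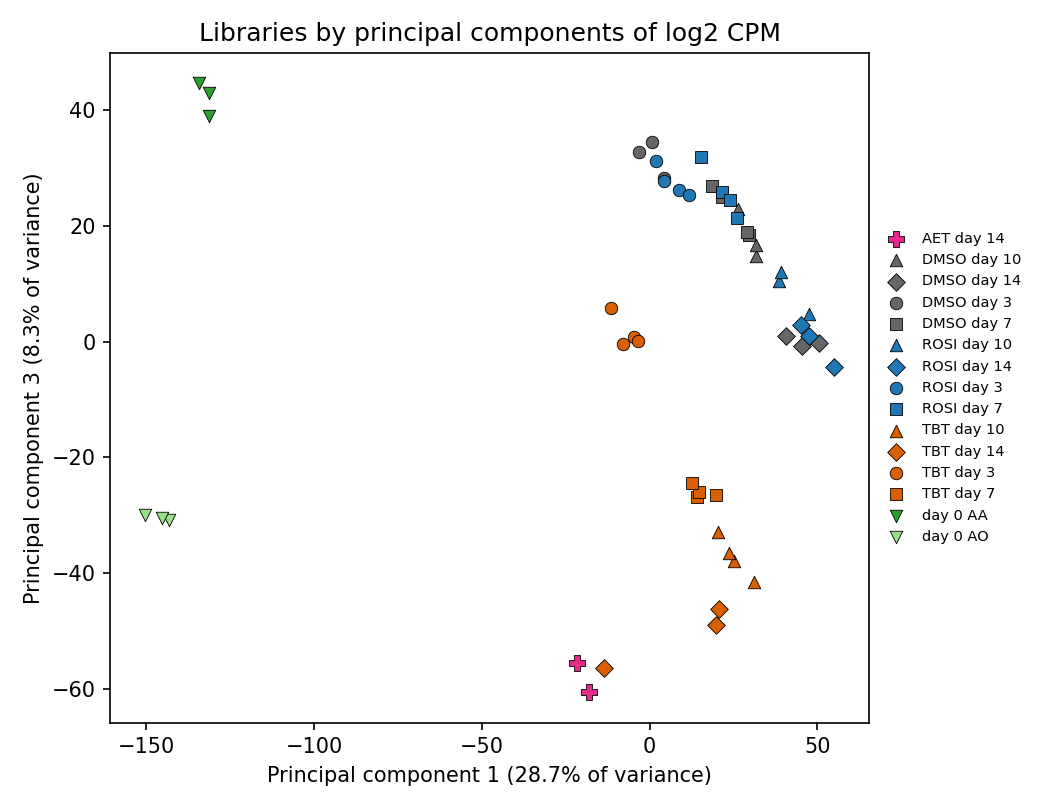
Each point is a library, placed by its scores on the first (horizontal, 28.7% of the variance) and the third (vertical, 8.3%) principal components of log2 CPM, with colour for the group. Day 0 lies at the left, between -150.4 and -131.2, and the AET libraries (-60.6 to -55.5) and the TBT libraries of day 14 (-56.4 to -46.2) lie at the bottom.

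The DMSO libraries were compared with day 0 to describe differentiation without a test compound. Adipocyte genes rose and genes of inflammation and of the intermediate filaments fell. Adiponectin, ADIPOQ (ENSG00000181092.9, chromosome 3, 186842690 to 186858463 on GRCh38), had no reads in the 6 day 0 libraries and averaged 1.69 ± 0.334 CPM at day 3 and 179.6 ± 17.7 CPM at day 14. Against a floor of 3 counts over the day 0 group, that was at least 211-fold and at least 22423-fold higher. Haptoglobin (HP) was likewise at least 3010-fold higher at day 3, at 24.1 ± 5.63 CPM. PDK4, which restrains pyruvate dehydrogenase, rose from 0.05 ± 0.0631 CPM at day 0 to 106 ± 7.79 CPM at day 3 and 198 ± 24.0 CPM at day 14. The lipid droplet coat gene PLIN1 rose by 6.96 ± 0.20 and 8.61 ± 0.20 at days 3 and 14, CEBPA by 3.46 and 4.85, and PPARG by 1.04 and 1.3. FABP4 (ENSG00000170323.8, chromosome 8, 81478419 to 81483263) averaged 0.593 ± 0.222 CPM at day 3 and 27.1 ± 3.95 CPM at day 14.

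Of the 23 measured adipocyte genes, 18, 21, 19 and 22 rose at days 3, 7, 10 and 14 (18, 22, 19 and 22 adjusted over the list alone), and none fell. The list test (camera) gave adjusted p = 0.00234, 0.000432, 0.000205 and 0.000102 with an estimated correlation. Glucocorticoid response genes rose in 12, 13, 12 and 13 of 14 cases (12, 13, 12 and 13 adjusted over the list alone, estimated-correlation adjusted p = 0.0088, 0.00811, 0.0079 and 0.0107). FKBP5, an HSP90 cochaperone, rose by 5.31 ± 0.07 and 6.02 ± 0.08 at days 3 and 14, and TSC22D3 by 4.90 and 5.45. Metallothionein genes, which bind zinc and copper, rose in 8, 8, 7 and 6 of 8 cases (8, 8, 7 and 6 adjusted over the list alone). Their estimated-correlation p was 0.0088, 0.0258, 0.0484 and 0.187, which ended the call at day 14. The day 10 call was also lost without DMSO replicate 1 (0.0523) or 2 (0.0748), AA replicate 3 (0.0502), or AO replicate 1 (0.0566) or 3 (0.0551). MT1X rose by 6.94 at day 3 and 5.06 at day 14, and MT2A by 3.41 and 0.98. PPAR target genes rose in 12, 12, 11 and 12 of 18 cases and fell in 4, 4, 3 and 4 (estimated-correlation adjusted p = 0.0151, 0.0691, 0.036 and 0.0348). Adjusted over the list alone, 13, 12, 12 and 12 rose and 4, 4, 3 and 4 fell. That call was lost without DMSO replicate 2 at day 10 (0.0923) and without DMSO replicate 1 at day 14 (0.0593). ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.71 and 2.79 at days 3 and 14.

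At each of the 4 days, 14 of 17 inflammation genes fell and 3 rose (the same counts adjusted over the list alone, estimated-correlation adjusted p = 0.0151, 0.0258, 0.0181 and 0.0154). IL1B fell by 5.44 ± 0.28 at day 3 on the log2 scale, LIF by 5.97 and CXCL8 by 5.89. Intermediate filament and lamina genes fell in 12, 12, 11 and 12 of 14 cases and rose in 2, 1, 1 and 1 (the same counts adjusted over the list alone, adjusted p = 0.0151, 0.0133, 0.02 and 0.0107). KRT18 changed by -2.95 and -6.02 at days 3 and 14, and LMNA by -1.17 at day 3. Actin cytoskeleton genes fell in 28, 29, 26 and 32 of 33 cases (29, 29, 26 and 32 adjusted over the list alone), with adjusted p = 0.0386, 0.0638, 0.0715 and 0.0256 with an estimated correlation. At day 3 that call was lost without DMSO replicate 3 (0.0502), and with the AO libraries alone as day 0 (0.616). ACTA2 changed by -1.22 ± 0.11 and -2.11 ± 0.12, TAGLN by -1.31 and -2.02, and the tubulin gene TUBB6 by -1.78 and -2.32. Epithelial genes fell in 4, 4, 6 and 6 of 7 cases (4, 4, 6 and 7 adjusted over the list alone, adjusted p = 0.147, 0.116, 0.0715 and 0.0107), and MUC1 fell by 2.97 at day 14. The collagen gene COL1A1 changed by 1.62 at day 3 and -1.4 at day 14. Against the AA libraries alone the day 3 value of COL1A1 was 0.07 (adjusted p = 0.676), and against the AO libraries alone the day 14 value was 0.16 (0.276) and the day 3 value of TAGLN 0.05 (0.737).

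Further lists moved under the preset correlation and lost the call with an estimated correlation. Tubulin and microtubule genes fell in 16, 17, 16 and 17 of 22 cases (16, 17, 16 and 17 adjusted over the list alone, adjusted p = 0.088, 0.14, 0.166 and 0.101 with an estimated correlation). Proliferation genes fell in 20, 22, 20 and 23 of 25 cases (20, 22, 20 and 23; adjusted p = 0.315, 0.29, 0.3 and 0.132), with MKI67, a marker of cycling cells, at -1.98 ± 0.31 and -2.94 ± 0.34 at days 3 and 14. Interferon genes fell in 11, 14, 15 and 15 of 17 cases (11, 15, 15 and 15; adjusted p = 0.332, 0.133, 0.105 and 0.0684), and cholesterol synthesis genes in 15, 14, 14 and 15 of 18 (15, 14, 14 and 15; adjusted p = 0.088, 0.155, 0.166 and 0.104). Focal adhesion and integrin genes fell in 15, 16, 17 and 18 of 21 (15, 16, 17 and 19; adjusted p = 0.0952, 0.0691, 0.085 and 0.0521), and YAP TEAD targets in 12, 12, 12 and 11 of 18 (12, 12, 12 and 11; adjusted p = 0.0554, 0.116, 0.123 and 0.161). From day 7 to day 14, 17, 18 and 18 of 28 oxidative phosphorylation genes fell (17, 18 and 19; adjusted p = 0.487, 0.458 and 0.428). SCD changed by -2.37 and -1.48 at days 3 and 14 (0.16 at day 14 against the AA libraries alone, adjusted p = 0.376) and ABCA1 by 0.40 and -0.93. Over all 22905 genes tested, 12370, 13364, 12996 and 13725 changed at days 3, 7, 10 and 14, of which 6856, 7464, 7033 and 7669 rose. The AA and AO libraries that make up day 0 differed widely: with AA alone as day 0 the inflammation calls were lost at all 4 days (0.19 to 0.344) and the PPAR target calls at days 3, 10 and 14 (0.266 to 0.423). The intermediate filament calls of day 3 were lost with AA (0.0727) or AO (0.0532) alone, as were those of day 10 (0.06 and 0.0501) and the metallothionein call of day 10 (0.0964 and 0.0501), and the actin call of day 14 with AO alone (0.297). Without the libraries with contradicting labels, PPAR targets lost the call at days 3, 10 and 14 (0.0883, 0.136 and 0.104), metallothionein genes at days 7 and 10 (0.0529 and 0.104) and inflammation genes at days 7 and 10 (0.0529 and 0.0571). So did actin genes at day 3 (0.0744; 0.062 on the most common flow cell alone) and intermediate filament genes at day 10 (0.0571). Under the groups of the tags, PPAR targets lost it at days 3, 10 and 14 (0.15 to 0.352), actin genes at days 3 and 14 (0.352 and 0.239), inflammation genes at all 4 days (0.252 to 0.355) and metallothionein genes at days 7 and 10 (0.0631 and 0.0741). Fitted on the compared libraries alone, all 7 list calls of day 3 (0.054 to 0.36) and 6 of the 7 of day 14 (0.108 to 0.284) were lost, with those of metallothionein (0.114) and inflammation (0.173) genes at day 7 and of PPAR targets (0.0858) and metallothionein genes (0.0596) at day 10.

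TBT was set against DMSO on the same day to ask what the compound adds to differentiation. Genes of cholesterol and fatty acid synthesis and targets of the liver X receptors (LXR) rose at all 4 days. Stearoyl-CoA desaturase, SCD (ENSG00000099194.5, chromosome 10, 100347124 to 100364834 on GRCh38), rose by 4.20 ± 0.17, 3.61 ± 0.15, 3.72 ± 0.17 and 4.58 ± 0.18 at days 3, 7, 10 and 14. Its level was 3982 ± 282 CPM with TBT and 216 ± 10.2 CPM with DMSO at day 3, and 9550 ± 4590 against 399 ± 78.3 CPM at day 14. The cholesterol exporter ABCA1 (ENSG00000165029.15, chromosome 9, 104781002 to 104928237) rose by 1.88 ± 0.07, 2.55 ± 0.07, 2.78 ± 0.08 and 3.5 ± 0.08, from 90.1 ± 3.95 to 1016 ± 53.6 CPM at day 14. The fatty acid binding protein gene FABP3 rose by 6.21, 4.37, 5.53 and 8.36, from 0.232 ± 0.108 to 76.7 ± 17.4 CPM at day 14.

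All 18 measured cholesterol synthesis genes rose at days 3, 7 and 14, and 17 rose at day 10 (18, 18, 18 and 18 adjusted over the list alone). With an estimated correlation the list gave adjusted p = 2.17e-08, 7.68e-05, 7.61e-05 and 4.68e-05. DHCR7, which makes cholesterol from 7-dehydrocholesterol, rose by 3.65, 3.10, 3.08 and 4.14, MVD by 2.33, 1.47, 1.37 and 2.34 and INSIG1 by 2.11, 1.76, 1.97 and 2.64. Lipogenesis genes rose in 14, 16, 14 and 14 of 17 cases (14, 16, 15 and 15 adjusted over the list alone, adjusted p = 8.62e-08, 9.15e-05, 0.000172 and 8.13e-05). The desaturase genes FADS1 and FADS2 rose by 2.98, 1.71, 2.10 and 3.38 and by 2.38, 1.89, 1.78 and 2.71, and acetyl-CoA carboxylase ACACA by 1.3, 1.35 and 1.83 from day 7. LXR targets rose in 10, 9, 10 and 10 of 11 cases (10, 10, 10 and 10 adjusted over the list alone, adjusted p = 4.73e-07, 2.85e-05, 4.47e-05 and 4.68e-05). Among them, SREBF1, the regulator of fatty acid synthesis genes, rose by 2.34, 2.96, 2.88 and 3.32, LPCAT3 by 1.71, 1.52, 1.61 and 2.18, and APOE by 3.05 and 3.07 at days 7 and 10. Fitted on the libraries of the compared groups alone, these 3 lists gave estimated-correlation p values of 0.074 to 0.0902 at day 10 and 0.0686 to 0.235 at day 14. With groups as the tags give them, the calls at days 7, 10 and 14 were also lost (0.1 to 0.965).

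PPAR target genes rose in 10, 10, 10 and 13 of 18 cases and fell in 0, 0, 0 and 2 (11, 12, 11 and 14 rose adjusted over the list alone, adjusted p = 1.33e-06, 7.68e-05, 0.000172 and 7.02e-05). ANGPTL4 rose by 2.31, 2.78, 2.20 and 2.35, PDK4 by 2.02, 2.11, 1.73 and 2.28, and PLIN2 by 1.4, 1.25 and 2.16 from day 7. This call too was lost at day 10 (0.0902) and day 14 (0.13) with the compared groups fitted alone. Retinoic acid targets rose in 6, 8 and 7 of 10 cases at days 3, 7 and 10 (7, 8 and 8 adjusted over the list alone, adjusted p = 6.73e-05, 0.0136 and 0.0394). At day 14, 4 rose and 2 fell (adjusted p = 0.529). CYP26B1, which breaks down retinoic acid, rose by 3.51, 2.76 and 2.28, and TGM2 by 1.82, 1.64, 1.51 and 2.67, while the receptor gene RARB rose by 1.27 at day 3 and changed by -1.12 at day 14. The day 10 call of this list was lost without DMSO replicate 2 (0.113), DMSO replicate 3 (0.0784) or TBT replicate 3 (0.0675), without the libraries with contradicting labels (0.319) and with the compared groups fitted alone (0.192). With groups as the tags give them, the calls of both lists were lost at days 7 and 10 (0.121 and 0.965), and that of PPAR targets at day 14 (0.16).

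**Figure D2:**
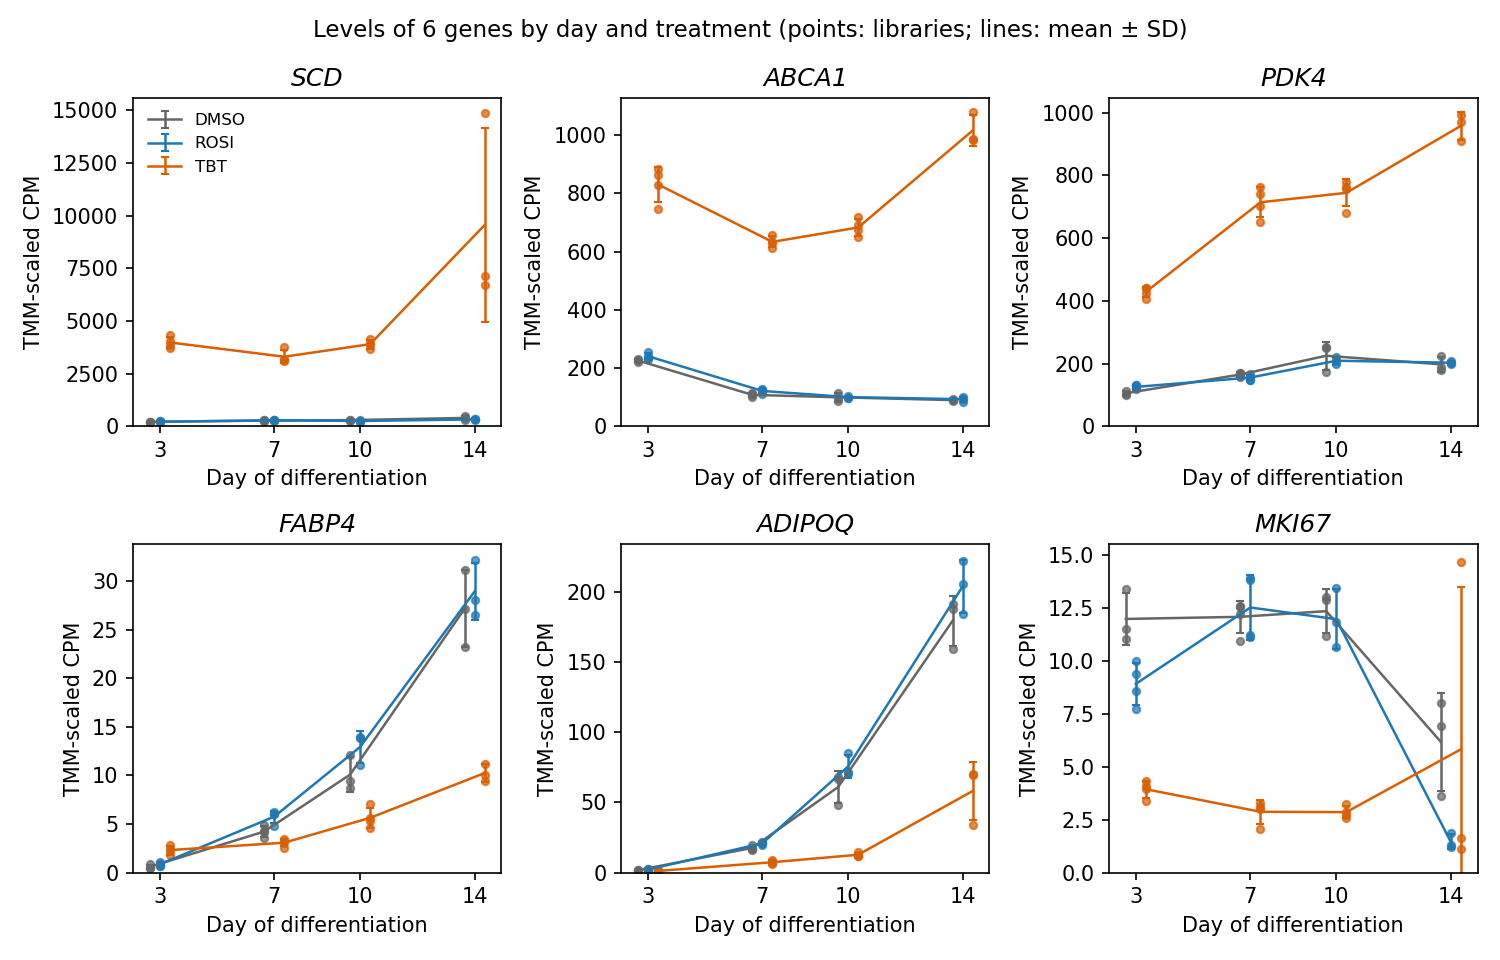
Level of SCD, ABCA1, PDK4, FABP4, ADIPOQ and MKI67 in TMM-scaled CPM (vertical) by day of differentiation (horizontal) with DMSO (grey), ROSI (blue) and TBT (orange); points are libraries and lines join means ± SD. SCD and ABCA1 were higher with TBT at all 4 days, and ADIPOQ at day 14 averaged 58.2 ± 20.9 CPM with TBT and 179.6 ± 17.7 CPM with DMSO.

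Adipocyte markers moved both ways. PPARG (ENSG00000132170.19, chromosome 3, 12287368 to 12434356), the regulator of fat-cell formation, rose by 0.32 ± 0.08, 0.44 ± 0.07, 0.47 ± 0.08 and 0.59 ± 0.08 at days 3, 7, 10 and 14. PLIN4 rose by 1.91, 2.14, 1.92 and 1.91, and PLIN1 by 0.93, 1.15 and 1.12 until day 10, with 0.40 ± 0.16 at day 14 (adjusted p = 0.0505; 0.72 and 4.09e-07 without TBT replicate 3; 0.0421 with RLE size factors and 1.18e-05 without the low-count filter). FABP4 rose by 2.02 ± 0.21 at day 3 and was lower at days 10 and 14, at -0.84 and -1.41. ADIPOQ was lower at days 7, 10 and 14, at -1.26, -2.26 and -1.63, and did not pass at day 3 (-0.57 ± 0.26, adjusted p = 0.204; 0.0485 without TBT replicate 3 and 0.000441 without the low-count filter). CEBPA was higher at day 7, at 1.55, and lower at day 14, at -1.93 (0.785 ± 0.127 against 2.99 ± 0.431 CPM). LPL rose by 0.92 at day 7 and was lower at day 14, at -1.12. Over the list, 8, 9, 6 and 4 of 23 adipocyte genes rose and 4, 6, 10 and 12 fell (adjusted p = 0.612, 0.719, 0.403 and 0.121 with an estimated correlation). Adjusted over the list alone, 8, 9, 6 and 5 rose and 5, 7, 10 and 12 fell. At day 14, GPD1 was at -2.96 (-3.57 without TBT replicate 2), the lipase gene LIPE at -2.44, and PCK1 at -4.76.

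Most proliferation genes were lower with TBT until day 10. At days 3, 7 and 10 they fell in 17, 18 and 20 of 25 cases (21, 19 and 20 adjusted over the list alone), with adjusted p = 0.0612, 0.102 and 0.088 with an estimated correlation. MKI67 (ENSG00000148773.13, chromosome 10, 128096659 to 128126385) was at -1.61 ± 0.33, -2.08 ± 0.32 and -2.11 ± 0.34, and the ribonucleotide reductase gene RRM2 at -1.55, -2.28 and -1.91. At day 14, MKI67 averaged 5.81 ± 7.67 CPM with TBT and 6.17 ± 2.30 CPM with DMSO (adjusted p = 0.961), and 3 proliferation genes rose and 4 fell (3 and 3 adjusted over the list alone, adjusted p = 0.719). Without TBT replicate 3, the library that lay near the AET group, MKI67 was at -2.12 at day 14 (adjusted p = 2.75e-10). The proliferation list then had a median of -0.82 (adjusted preset-correlation p = 1.45e-07), and was not called, with adjusted p = 0.0824 with an estimated correlation.

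Genes of autophagy and the lysosome rose in 11 and 11 of 16 cases at days 7 and 14 (11 and 11 adjusted over the list alone, adjusted p = 0.0297 and 0.0414 with an estimated correlation), and in 4 at day 10 (7; adjusted p = 0.222). The selective autophagy receptor SQSTM1 rose by 0.35, 1.12, 0.85 and 1.18, and GPNMB by 1.41, 1.5 and 2.77 from day 7. These calls were lost without DMSO replicate 2 (0.0514), TBT replicate 1 (0.0507) or TBT replicate 3 (0.0533) at day 7, and without DMSO replicate 1 (0.0677) or 2 (0.0554) at day 14. Both were lost with the compared groups fitted alone (0.164 and 0.307) and with groups as the tags give them (0.121 and 0.1). That of day 14 was also lost without the libraries with contradicting labels (0.0528), with AET pooled into TBT (0.0544) and on the most common flow cell alone (0.0506). Oxidative stress genes rose in 7, 9, 10 and 13 of 18 cases (9, 9, 10 and 13 adjusted over the list alone), with adjusted p = 0.104, 0.321, 0.222 and 0.166 with an estimated correlation. The pentose phosphate enzyme gene TKT rose by 0.82, 0.67, 0.49 and 0.61, and heme oxygenase HMOX1 by 0.83, 0.72 and 0.98 from day 7. Unfolded protein and integrated stress genes rose in 11 of 20 cases at day 14 (13; adjusted p = 0.308). Of the heat shock genes, 3 and 4 of 14 rose at days 3 and 14 (4 and 4; adjusted p = 0.559 and 0.486).

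Of the cytoskeletal genes, which the series title names, more fell than rose at days 7 and 10 and more rose than fell at day 14. Actin cytoskeleton genes fell in 12 and 16 of 33 cases at days 7 and 10 and rose in 7 and 4. At day 14, 16 rose and 4 fell. Adjusted over the list alone, 15 and 17 fell and 17 rose at those days, with adjusted p = 0.574, 0.614 and 0.308 with an estimated correlation. The actin genes ACTB, at -0.92 ± 0.08 and -0.72 ± 0.08, and ACTG1, at -0.84 and -0.97, were lower at days 7 and 10. The smooth muscle actin binding gene TAGLN rose by 0.72, 0.90 and 1.64 at days 3, 10 and 14, and MYL9 by 0.64 and 1.76 at days 7 and 14. Tubulin and microtubule genes fell in 12 and 8 of 22 cases at days 7 and 10, and 13 rose at day 14 (13, 9 and 14 adjusted over the list alone, adjusted p = 0.477, 0.614 and 0.308). The TBT libraries of day 10 held 3.264 to 5.604% of their reads on long noncoding genes, against 2.508 to 2.809% for DMSO. With that share as a term the actin and tubulin medians of day 10 were -0.09 and -0.10 (adjusted preset-correlation p = 0.168 and 0.425), against -0.20 and -0.24 without it (0.00614 and 0.0354). TUBB6 was lower at days 7 and 10, at -0.38 and -0.44, and higher at day 14, at 0.55 (0.23 without TBT replicate 3, adjusted p = 0.0372). It did not pass at day 7 (0.0519) or 10 (0.0556) without the libraries with contradicting labels, or at day 14 with the compared groups fitted alone (0.0716). TUBA4A rose by 1.08, 1.54 and 2.5 at days 7, 10 and 14 (1.80 at day 14 without TBT replicate 3). The intermediate filament gene VIM was lower at all 4 days (-0.56, -0.50, -0.98 and -0.64), while its list went 0, 2, 1 and 5 up and 4, 5, 5 and 4 down of 14 (adjusted p = 0.699, 0.869, 0.38 and 0.887). YAP TEAD targets fell in 10 and 11 of 18 cases at days 7 and 10 (10 and 12 adjusted over the list alone, adjusted p = 0.341 and 0.0773), with AMOTL2 at -0.45, -0.63, -0.91 and -0.87 over the 4 days.

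Collagen and matrix genes rose in 15 and 14 of 24 cases at days 7 and 14 (15 and 15 adjusted over the list alone, adjusted p = 0.341 and 0.175 with an estimated correlation). COL1A1 rose by 0.62 and 1.02 at those days, and periostin, POSTN, by 0.95, 1.02, 1.67 and 2.46 at the 4 days (1.87 at day 14 without TBT replicate 3). Focal adhesion and integrin genes rose in 12 of 21 cases at day 14 (13; adjusted p = 0.205), and inflammation genes in 8 of 17 (9; adjusted p = 0.166), with CCL2 at 1.10, 0.64, 1.14 and 1.47 over the 4 days. Mesenchymal stem cell surface genes rose in 8 of 13 cases at day 14 (8; adjusted p = 0.175), THY1 by 1.96. Glucocorticoid response genes fell in 11 and 11 of 14 cases at days 10 and 14 (12 and 11; adjusted p = 0.127 and 0.175), with FKBP5 at -0.72 at day 14. Chondrocyte genes rose in 4 of 9 cases at day 10 (4; adjusted p = 0.0393), with SOX9 at 0.92, a call lost without DMSO replicate 2 (0.0696) or TBT replicate 3 (0.0675). It was also lost without the libraries with contradicting labels (0.254), with the compared groups fitted alone (0.201) and with groups as the tags give them (0.965). At day 14, of the other lists, early adipogenic regulators had 4 genes higher and 3 lower of 14 (adjusted p = 0.816), p53 targets 5 and 3 of 18 (adjusted p = 0.816), interferon 5 and 1 of 17 (adjusted p = 0.597), metallothionein 3 and 1 of 8 (adjusted p = 0.549) and oxidative phosphorylation 6 and 0 of 28 (adjusted p = 0.748).

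Markers of other cell types were few. At day 14 with TBT, thermogenic genes had 2 higher and 0 lower of 10 measured (adjusted p = 0.696), osteoblast genes 1 and 3 of 8 (adjusted p = 0.166), and skeletal muscle genes 1 and 1 of 5 (adjusted p = 0.988). Endothelial genes had 4 and 0 of 9 (adjusted p = 0.175), blood and macrophage genes 1 and 1 of 5 (adjusted p = 0.646), epithelial genes 1 and 0 of 7 (adjusted p = 0.56), and nervous and glial genes 0 and 1 of 6 (adjusted p = 0.923). Adjusted over each list alone the counts were the same for these 7 lists. Over all 22905 genes tested, TBT changed 1837, 5557, 5660 and 6769 at days 3, 7, 10 and 14, with 952, 2820, 2796 and 3997 higher. At least 2-fold, 199, 575, 672 and 936 were higher and 138, 360, 372 and 811 lower. The day 3 count was 1138 without DMSO replicate 3. With groups as the tags give them the counts were 283, 579, 0 (458 at an unadjusted p under 0.05) and 3914, and with the compared groups fitted alone the day 10 and day 14 counts were 3537 and 3944. Without the libraries with contradicting labels, 2858 genes were higher and 1495 lower at day 10.

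**Figure D3:**
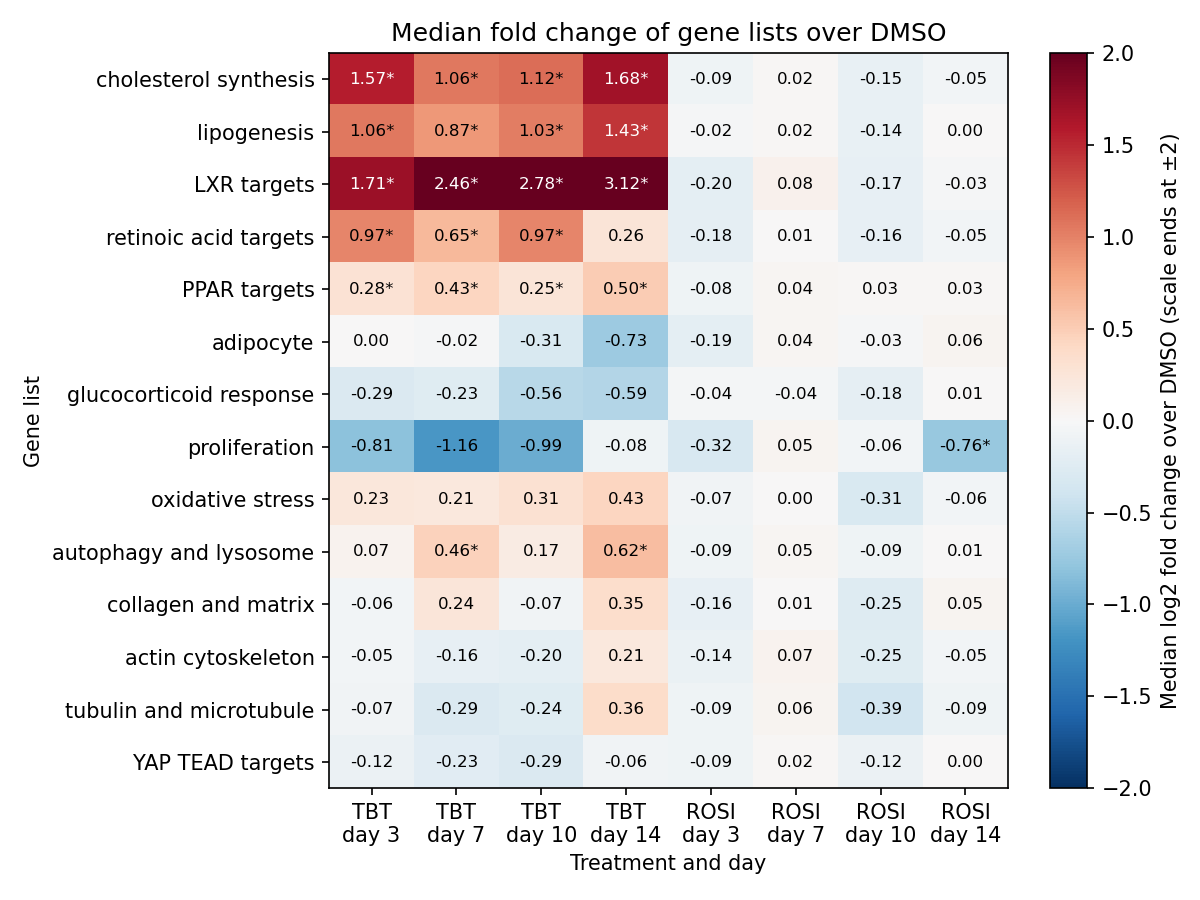
Median log2 fold change against DMSO (colour) of 14 gene lists (rows) for TBT and ROSI at days 3, 7, 10 and 14 (columns); an asterisk marks an adjusted p under 0.05 with an estimated correlation. The LXR list with TBT has medians of 1.71 at day 3 and 3.12 at day 14.

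ROSI was compared with DMSO as the reference activator of PPARG. At day 3, 48 genes changed, 6 higher and 42 lower. The acute phase genes SAA1 and LBP were lower, at -1.52 ± 0.18 and -1.23 ± 0.20, as were APOE at -1.22 ± 0.18, CHI3L1 at -1.11, the cartilage matrix gene COMP at -0.95 and ALPL at -0.95. The small heat shock gene HSPB7 was higher by 0.77. SAA1 averaged 78.4 ± 8.99 CPM with ROSI and 225 ± 90.6 CPM with DMSO. The count was 5 and 22 without DMSO replicates 1 and 4, and 74, 19 and 15 without ROSI replicates 1, 3 and 4. Without DMSO replicate 1, LBP, ALPL and COMP did not pass (adjusted p = 0.0605, 0.0605 and 0.637), nor did COMP with the compared groups fitted alone (0.0766). All 10 lists that moved under the preset correlation, each lower, lost the call with an estimated correlation (adjusted p = 0.351 to 0.505). Without the low-count filter, in a fit that tests more genes of low count, 517 genes passed. DESeq2 called 138 genes, and 26 passed with the noncoding share of each library as a term. No gene passed with groups as the tags give them (1260 at an unadjusted p under 0.05), and these 7 genes had adjusted p = 0.892 to 0.997.

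At day 7 edgeR called 0 genes with ROSI and DESeq2 called 0, with 998 and 1076 at an unadjusted p under 0.05. Without the low-count filter edgeR called 19. FABP4 averaged 5.76 ± 0.626 CPM with ROSI and 4.22 ± 0.563 CPM with DMSO at that day, a difference that did not pass (adjusted p = 0.961). ADIPOQ likewise averaged 20.8 ± 0.994 and 17.6 ± 1.54 CPM (adjusted p = 0.961), and PPARG 27.5 ± 2.74 and 26.2 ± 1.27 CPM (adjusted p = 0.961). At day 14, 13 genes changed and 12 of them were lower. Genes of DNA synthesis and cell division were among them, with RRM2 at -2.39 ± 0.34, and MKI67 at -2.08 ± 0.40 (1.45 ± 0.346 against 6.17 ± 2.30 CPM). Of the 25 proliferation genes, 5 fell (14 adjusted over the list alone, adjusted p = 0.0296 with an estimated correlation, and 0.0578 from fry). The first p was 0.314 without DMSO replicate 1, 0.0734 without DMSO replicate 2, 0.119 and 0.213 without ROSI replicates 1 and 3, and 0.053 with the replicate number as a block. It was 0.0562 without the low-count filter, 0.0577 with the noncoding share as a term, 0.0677 without the libraries with contradicting labels, 0.255 with groups as the tags give them, 0.263 on the most common flow cell alone and 0.982 with the compared groups fitted alone. COMP was again lower, at -1.24 (adjusted p = 0.106 without ROSI replicate 3, and 0.137 on the most common flow cell alone). MKI67 did not pass without DMSO replicate 1 (0.37) or 2 (0.152), or ROSI replicate 1 (0.151), 2 (0.0599) or 3 (0.317), or on the most common flow cell alone (0.137). The day 14 count was 2, 3 and 56 without DMSO replicates 1, 2 and 3, and 6 and 2 without ROSI replicates 2 and 3. It was 0 with groups as the tags give them (340 at an unadjusted p under 0.05). Without the low-count filter it was 121, with DESeq2 36 and without the libraries with contradicting labels 47.

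At day 10, ROSI changed 2235 genes, 1012 higher and 1223 lower. Adipocyte genes that passed were AQP7, a glycerol channel gene, at 0.76 ± 0.19, ACVR1C at 0.82 ± 0.21 and the lipase gene PNPLA2 at -0.33 ± 0.09. Genes that were lower included COMP (-1.20), the Wnt inhibitor gene DKK1 (-1.63), ID3 (-1.39), CRISPLD2 (-0.73) and the metallothionein MT2A (-0.60). Actin cytoskeleton genes fell in 14 of 33 cases, tubulin and microtubule genes in 8 of 22, oxidative stress genes in 10 of 18 and collagen and matrix genes in 8 of 24 (21, 15, 13 and 10 adjusted over the list alone). For each of these 4 lists adjusted p = 0.279 with an estimated correlation. Of the genes called higher, 39.5% were not protein-coding, against 2.3% of those called lower and 36.9% of all tested, and the ROSI libraries of this day held 3.301 to 5.09% of their reads on long noncoding genes, against 2.508 to 2.809% for DMSO. The count was 18 without ROSI replicate 3 (2 higher and 16 lower), 705 without DMSO replicate 1 and 60 with the noncoding share as a term (24 and 36). The balance of higher and lower genes was not stable. Without the libraries whose tags contradict their titles, which leaves 1 library a side, 80 genes passed, 78 higher and 2 lower. With the compared groups fitted alone 417 passed, 314 higher and 103 lower, and without DMSO replicate 2 620 were higher and 1222 lower. The count was 0 with groups as the tags give them (1550 at an unadjusted p under 0.05). Without ROSI replicate 3, AQP7, ACVR1C, PNPLA2 and MT2A did not pass (adjusted p = 0.204, 0.213, 0.167 and 0.124). Without DMSO replicate 2, AQP7 (0.097) and DKK1 (-0.48, 0.0767) did not pass and ID3 was at -0.74, and PNPLA2 did not pass without DMSO replicate 1 (0.0763). Without the libraries with contradicting labels none of these 8 genes passed: COMP was at -0.69 (0.299), DKK1 at -0.33 (0.592), ID3 at -0.82 (0.199), CRISPLD2 at -0.43 (0.13), MT2A at -0.62 (0.24), AQP7 at 0.19 (0.83), ACVR1C at 0.55 (0.464) and PNPLA2 at -0.41 (0.226). With the noncoding share as a term AQP7 (0.222), ACVR1C (0.253), PNPLA2 (0.308) and MT2A (0.118) did not pass, and with the compared groups alone AQP7 (0.0502), ACVR1C (0.0735) and PNPLA2 (0.0926) did not.

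TBT and ROSI were also compared directly. TBT libraries were higher in lipid synthesis genes on every day. SCD was higher by 4.18 ± 0.15, 3.52 ± 0.15, 3.94 ± 0.17 and 4.86 ± 0.18 at days 3, 7, 10 and 14, ABCA1 by 1.78, 2.38, 2.77 and 3.45, PDK4 by 1.77, 2.20, 1.83 and 2.24 and ANGPTL4 by 2.37, 2.67, 2.13 and 2.40. ADIPOQ was lower with TBT at days 7, 10 and 14, at -1.51, -2.57 and -1.81, and PPARG was higher by 0.37, 0.37, 0.39 and 0.54 (0.34 at day 10 without the libraries with contradicting labels, adjusted p = 0.154). LXR targets were higher in 10, 9, 10 and 10 of 11 cases (11, 10, 10 and 10 adjusted over the list alone), cholesterol synthesis genes in 18, 17, 17 and 18 of 18 (18, 17, 18 and 18), lipogenesis genes in 14, 15, 14 and 15 of 17 (15, 15, 14 and 16) and PPAR targets in 12, 9, 10 and 12 of 18 (12, 10, 10 and 12). With an estimated correlation the adjusted p of these 4 lists lay between 8e-07 and 0.000155, and fitted on the compared libraries alone it was 0.186 to 0.242 at day 10 and 0.149 to 0.166 at day 14. Retinoic acid targets were higher in 8, 8 and 8 of 10 cases at days 3, 7 and 10 (8, 8 and 8; adjusted p = 7.21e-05, 0.0167 and 0.0083). Oxidative stress genes were higher in 15 of 18 at day 10 (15; adjusted p = 0.0083) and chondrocyte genes in 5 of 9 (6; adjusted p = 0.00215). The day 10 p of these 3 lists was 0.271, 0.271 and 0.186 with the compared libraries fitted alone, and that of retinoic acid targets 0.0811 without the libraries with contradicting labels. The groups of the tags ended the calls of LXR, cholesterol synthesis, lipogenesis and PPAR lists at days 7, 10 and 14 (0.128 to 0.209), and those of retinoic acid targets (0.132 and 0.141 at days 7 and 10), oxidative stress (0.693) and chondrocyte genes (0.209). Proliferation genes fell in 19 of 25 at day 7 (20; adjusted p = 0.0633), and adipocyte genes in 12 of 23 at day 14 (13; adjusted p = 0.0559). Autophagy and lysosome genes were higher in 12, 9 and 11 of 16 at days 7, 10 and 14 (12, 10 and 11; adjusted p = 0.0313, 0.0473 and 0.0448). That call was lost at day 7 without TBT replicate 1 (0.0549) or 3 (0.0575), and at day 14 without ROSI replicate 1 (0.0611) or TBT replicate 1 (0.0503). At day 10 it was lost without ROSI replicate 3 (0.0717) or TBT replicate 1 (0.0524), 2 (0.0534) or 3 (0.0535), with the flow cell as a term (0.0503), and at day 14 on the most common flow cell alone (0.0594). At days 7, 10 and 14 it was lost without the libraries with contradicting labels (0.0691, 0.0841 and 0.0776), with the compared libraries fitted alone (0.0857, 0.284 and 0.274) and with groups as the tags give them (0.132, 0.209 and 0.128). In all, 3604, 5380, 4565 and 7137 genes differed between TBT and ROSI at days 3, 7, 10 and 14.

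Both treatments were compared with the same DMSO libraries, so their fold changes share chance values. Across genes, the fold changes of TBT and ROSI correlated at r = 0.329, 0.385, 0.441 and 0.226 at days 3, 7, 10 and 14. Simulated groups with no effect, set against the same DMSO libraries, gave 0.501, 0.539, 0.497 and 0.481. The observed covariances were 0.1113, 0.1188, 0.2117 and 0.1076, against 0.1156, 0.092, 0.1091 and 0.1305 in the simulations. With the 4 DMSO libraries of day 7 split between the treatments, r was 0.025 and the covariance 0.0111. At day 10, 131 genes were called higher with both treatments, where independent lists give 22.6, and 46 lower with both, where they give 13.5, while 41 were called in opposite directions. At day 3, 0 were called higher with both (0.4 by independence), 12 lower with both (4.3) and 35 in opposite directions. At days 7 and 14 no gene was shared in 1 direction, but ROSI called only 0 and 1 genes in these fits. Simulated groups with no effect gave 0.05 higher and 0 lower with both at day 10. On average they called only 0.15 and 0.1 genes higher, and 0.4 and 0.2 lower, for TBT and ROSI. An overlap near 0 was thus fixed beforehand and sets no bound for the observed counts. Part of the day 10 excess may come from the shared DMSO libraries, which numbered 3 at day 10 and were not split. Both treatments also held more reads on long noncoding genes at that day. The shares were 3.301 to 5.09% with ROSI and 3.264 to 5.604% with TBT, against 2.508 to 2.809% with DMSO. These fits had no term for that share, and its part in the excess was not tested. Genes are not independent replicates, and these counts come from fits of 1 day at a time.

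The change of the TBT effect between days 3 and 14 was tested as an interaction. The fold change of 2485 genes differed between the days, 1882 higher and 603 lower at day 14. The effect on ABCA1 was higher at day 14 by 1.62 ± 0.10, on MKI67 by 1.58 ± 0.49, on TAGLN by 0.92, on COL1A1 by 0.86 and on TUBB6 by 0.76. It was lower on FABP4, at -3.43 ± 0.26, on LPL, at -2.21 ± 0.38, on CEBPA, at -1.60, and on ADIPOQ, at -1.06. Of the 23 adipocyte genes, 8 had a lower effect at day 14 (11 adjusted over the list alone, adjusted p = 0.0168 with an estimated correlation), and 6 of 11 LXR targets a higher one (6; adjusted p = 0.0168). Without TBT day 14 replicate 3 both gave adjusted p = 0.0617. Autophagy and lysosome genes had a higher effect in 10 of 16 cases (10; adjusted p = 0.0399). That p rose to between 0.0564 and 0.0778 on leaving out any of DMSO replicates 1 and 3 or TBT replicates 1, 2, 3 and 4 of day 3, or DMSO replicates 1 and 2 or TBT replicate 3 of day 14. It was 0.0551 without the libraries with contradicting labels, 0.0505 with AET pooled into TBT and 0.0547 on the most common flow cell alone. Autophagy and adipocyte genes both gave 0.215 with the compared libraries fitted alone and 0.162 with groups as the tags give them, and LXR targets gave 0.733 with the latter. Without TBT day 14 replicate 3, the value for MKI67 was -0.50 (adjusted p = 0.327), for TUBB6 0.45 (0.0046) and for ADIPOQ -0.78 (0.0592), and the gene count was 1638. MKI67 also did not pass without DMSO day 3 replicate 1 (0.0749), TBT day 3 replicate 3 (0.0548) or DMSO day 14 replicate 3 (0.105), nor ADIPOQ without DMSO (0.0668) or TBT (0.216) day 3 replicate 3. Without the libraries with contradicting labels MKI67 was at 1.32 (0.143), and with the compared libraries alone neither MKI67 (0.277) nor ADIPOQ (0.128) passed. Under the groups of the tags ABCA1 (0.222), MKI67 (0.263), TAGLN (0.592), COL1A1 (0.735), TUBB6 (0.268), FABP4 (-2.16, 0.0636), CEBPA (0.272) and ADIPOQ (0.11, 0.98) did not pass, and the gene count was 413. The gene count was 1552 without DMSO day 3 replicate 1. For ROSI the same interaction called 0 genes with edgeR and 0 with DESeq2, with 1403 and 1447 at an unadjusted p under 0.05. Without the low-count filter edgeR called 123, and with the compared libraries fitted alone 15.

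The 2 AET libraries, tagged like TBT day 14, were compared with the 3 TBT day 14 libraries to measure how far apart they lie. AET libraries had lower levels of the adipocyte genes GPD1 (-4.56; -3.95 without TBT replicate 2), CIDEC (-1.88), PLIN1 (-1.24) and ADIPOQ (-1.16 ± 0.20), and of the alcohol dehydrogenase ADH1B (-5.27). MKI67 was higher by 1.28 ± 0.38, and by 3.37 without TBT replicate 3, the library nearest to them. It did not pass without AET replicate 1 (adjusted p = 0.172) or 2 (0.0814) or TBT replicate 1 (0.231) or 2 (0.207), or on the most common flow cell alone (0.407). Proliferation genes were higher in 15 of 25 cases (20 adjusted over the list alone, adjusted p = 0.361 with an estimated correlation), and no list held its call with an estimated correlation. In all 2353 genes differed, 1221 higher and 1132 lower. The count was 501 (92 higher and 409 lower), 492 (110 and 382) and 5099 (2926 and 2173) without TBT replicates 1, 2 and 3, and 633 (171 and 462) and 1013 (524 and 489) without AET replicates 1 and 2. On the most common flow cell alone 4 genes were higher and 77 lower, so the balance was not stable. Fitted on these 5 libraries alone, edgeR called 0 genes, with 1931 at an unadjusted p under 0.05.

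The AA and AO libraries of day 0 carry the same tags and were compared with each other. Higher in AA libraries were COL1A1, at 3.12 ± 0.13 (13150 ± 345 against 1512 ± 33.6 CPM), TAGLN, at 2.72 ± 0.13, TUBB6 at 2.11, TUBA1A at 2.73 and KRT18 at 4.86. They had lower levels of the inflammation gene IL1B (-4.14), of SCD (-3.29; 356 ± 12.9 against 3482 ± 88.1 CPM), of SREBF1 (-1.91) and of PPARG (-0.77). Of the 17 inflammation genes, 14 were lower in AA (14 adjusted over the list alone, adjusted p = 0.0273 with an estimated correlation). That call was lost without the libraries with contradicting labels (0.0672) and with the AA and AO libraries fitted alone (0.321). Collagen and matrix genes were higher in 16 and lower in 6 of 24 cases (the same counts adjusted over the list alone, adjusted p = 0.442). Actin cytoskeleton genes were higher in 31 of 33 cases (31; adjusted p = 0.0746) and tubulin genes in 19 of 22 (19; adjusted p = 0.125). In all, 12694 genes differed, 6065 higher and 6629 lower in AA.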

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

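The tests on TBT day 14 replicate 3, those on the AA and AO libraries and the counts over other splits were chosen after the results were seen, and the term for the noncoding share and the fit on a single flow cell were added after the data were seen. So was the comparison of folds and SEs for ROSI at day 10.

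In a test of the difference, the effect of TBT differed between days 3 and 14 for 2485 genes. Among the panel genes it was higher at day 14 for the cholesterol exporter ABCA1 (1.62), MKI67 (1.58), TAGLN (0.92), COL1A1 (0.86), TUBB6 (0.76), HMOX1 (0.75) and ACTA2 (0.72). It was lower for the adipocyte genes ADIPOQ (-1.06), CEBPA (-1.60), LPL (-2.21) and FABP4 (-3.43). Without TBT day 14 replicate 3 the value for MKI67 was -0.50 and the count 1638, and without DMSO day 3 replicate 1 the count was 1552. With these libraries fitted alone, 8 of 100 splits within the days, the real one included, reached the real 1411 genes (highest other 4088). The 7 others all kept or mirrored the day 14 groups, and thus that day's effect, so the count cannot decide on chance. Splits that mixed those groups called at most 110.

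Among 126 sets, each 1 of 6 groups of 4 libraries and 1 of 21 quantities (the 18 panel genes, TERT, total reads and the noncoding share), 4 held a library far from the other 3, where chance gives about 1 in 20. ANGPTL4 was 62.43 CPM in ROSI day 7 replicate 3, and 55.34 to 55.98 in the others. SCD was 3760 CPM in TBT day 7 replicate 4, against 3108 to 3200. ACTA2 was 40.03 CPM in TBT day 7 replicate 4, against 38 to 38.24. TAGLN was 308.4 CPM in TBT day 3 replicate 2, against 378.9 to 392.1.

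ROSI against DMSO called 2235 genes at day 10 and 48, 0 and 13 at days 3, 7 and 14, where at day 7 edgeR called 0 with 998 at an unadjusted p under 0.05, and DESeq2 0 with 1076. With the noncoding share as a term 60 genes passed, so the RNA makeup of the libraries may account for most of the calls, though the shares do not overlap between ROSI (3.301 to 5.09%) and DMSO (2.508 to 2.809%) and the term thus removes part of the group difference. The count was 705 without DMSO replicate 1 and 18 without ROSI replicate 3, below the 10% of the calls set beforehand as the sign of a single library. Over the 2235 genes the median absolute log2 fold change was 0.362 (median SE 0.099), 0.223 (0.086) with the term, where the folds shrank, and 0.301 (0.11) without replicate 3, where 83.2% of the fold stayed and the SE grew. For that reason, found afterwards, the bound was not taken to settle whether 1 library made the pattern. Without ROSI replicate 1 or 2, in fits of the same size, the count was 2519 and 2250. These counts argue against the power lost with any 1 library as the whole cause of the drop to 18. By the bound and these counts, the calls depended on replicate 3. A lasting response cannot be told, as 60.5% of the genes kept their sign at day 14, between the bounds of 60% and 75%. At day 7, 20.2% had it, so most were reversed, which a response since day 7 does not give.

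TBT day 14 replicate 3 correlated at 0.9894 and 0.987 with the AET libraries and at 0.9812 and 0.9779 with the other TBT day 14 libraries, which had 0.9857 with each other. The flow cell is argued against, since r with the TBT library of its own flow cell minus r with the AET library of the other was -0.0059. So is depth, as its 68.9 M reads and the 68.1 and 45.5 M of AET interleave with 63.5 and 42.3 M in the others. AET against TBT day 14 called 2353 genes with it and 5099 without, a rise built in by leaving out the library nearest to AET. Replicate 3 scored 2.91 on TBT genes, nearer to AET (3.13 and 3.16) than to the others (1.88 and 1.95). TERT likewise lay nearer to AET. A wrong label still cannot be told apart from the place of a true replicate. A mixed or a slower culture was not tested, and what AET stands for is not given.

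AA and AO, both tagged as DMSO at day 0, differed in 12694 genes, with 14 of 17 inflammation genes lower in AA. The flow cell is argued against as the whole cause, since the libraries of the more common flow cell alone called 11541 genes. A brief stimulation at harvest, which would move fast genes and leave long-lived matrix transcripts, is argued against by a median absolute log2 fold change of 1.11 in the collagen and matrix list. The labels name no biological difference between the titles, and none besides that stimulation was tested.

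Other splits of the libraries, with the compared groups fitted alone, bear on each count of genes. For TBT against DMSO, 1 of 35 splits (the real one) called as many genes at day 3 (2336, highest other 1), day 7 (6242, highest other 0) and day 10 (3537, highest other 1). That share of 2.9% is the smallest that 35 splits can give and is not adjusted over the comparisons. It makes a chance split of these libraries unlikely, but bears on chance between cultures only if the replicates are separate cultures. The same holds for TBT against ROSI at day 3 (3517, highest other 0), day 7 (6491, highest other 0) and day 10 (4197, highest other 1308, which points to a structure among these libraries). At day 14 the 10 splits are too few for a share under 0.05, with 3944 genes for TBT against DMSO (highest other 0), 3373 for TBT against ROSI (highest other 0) and 19 for ROSI against DMSO (highest other 11). The same limit holds for ROSI at day 10 (417, highest other 0) and for AA against AO (13516, highest other 0). For ROSI at day 3, 2 of 35 splits called as many as the real 58 (highest other 132), so chance cannot be excluded. At day 7 the real split called 0, which all 35 reach by construction, so there were no calls for which to exclude chance. The highest other at day 7, with 1429, points to a structure of the samples. For DMSO against day 0, 3 of 84 splits reached the real 5867 at day 3, with AO against the rest at 6827. The real split alone reached its count in 1 of 100 at day 7 (7883, highest other 3341), 1 of 84 at day 10 (6392, AO against the rest 6028) and 1 of 84 at day 14 (7587, AA against the rest 6597). The shares of 3.6, 1, 1.2 and 1.2% are likewise not adjusted, and the AA and AO splits follow the titles of day 0. These fits hold day 0 as 1 group, with the AA and AO difference in its spread, and call fewer genes than the 13102, 13744, 12531 and 14336 of the compared libraries with separate AA and AO coefficients, so the splits bear on the former counts. For the change of the ROSI effect, 4 of 100 splits called at least the real 15, with 1321 as the highest other, which points to a structure of the samples. On all libraries edgeR and DESeq2 called 0 genes (1403 and 1447 at an unadjusted p under 0.05), and edgeR without the low-count filter 123. Chance was not excluded.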

How the results depend on the processing

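The term for the noncoding share and the fit on the most common flow cell alone were added after the data were seen; the other alternatives were fixed before.

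With RLE size factors no count of genes moved by over 1.5 times, and of the 660 list results, taken at the preset correlation, 649 kept their direction and side of the threshold, 7 lost the call and 4 gained it. Without the low-count filter, ROSI against DMSO gave 517 genes at day 3, 19 at day 7 and 121 at day 14, and the change of the ROSI effect 123; this fit tests more genes of low count, and 610 list results were the same, 1 lost and 49 gained. DESeq2 gave 138 and 36 genes for ROSI at days 3 and 14. With the noncoding share as a term, ROSI gave 26, 60 and 22 genes at days 3, 10 and 14, and 245 list results were the same, 14 lost and 5 gained. With the flow cell as a term the change of the ROSI effect gave 1 gene, and 654 list results were the same and 6 gained. On the most common flow cell alone, which leaves fewer libraries, TBT at day 3 gave 1176 genes, ROSI at day 14 1, TBT against ROSI at day 3 2113 and AET against TBT day 14 81. With AET pooled into TBT day 14 the change of the TBT effect gave 4024 genes.

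Fitted on the compared groups alone, which leaves fewer libraries to estimate the spread, TBT gave 3537 and 3944 genes at days 10 and 14, ROSI 417 at day 10, TBT against ROSI 3373 at day 14, AET against TBT day 14 0 (1931 at an unadjusted p under 0.05), the change of the TBT effect 1411 and that of the ROSI effect 15; 626 list results were the same, 16 lost and 18 gained. Without the libraries with contradicting labels, ROSI gave 80 and 47 genes at days 10 and 14, TBT against ROSI 1907 at day 10 and the change of the ROSI effect 2, and 65.7% of the TBT calls of day 10 were higher, against 49.4%; 611 list results were the same, 32 lost and 17 gained. For these changes, and for those with DESeq2 and the added terms, the cause was not tested. With the replicate number as a block no count moved by over 1.5 times; TBT gave 1925, 5765, 5387 and 6943 genes and ROSI 66, 0 (1099 unadjusted), 2895 and 13. The proliferation call with ROSI at day 14 had an adjusted estimated-correlation p of 0.053 under the block and up to 0.982, with the compared groups alone. Same-numbered libraries did not deviate together in every pair of any comparison (r of -0.005 to 0.171 for TBT at day 3, 0.018 to 0.13 for ROSI at day 10), so the numbers were not taken to pair the samples.

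With the groups of the tags, which the values of 9 of the 10 libraries go against (at day 10 in part by r with 1 library), TBT gave 283, 579, 0 (458 unadjusted) and 3914 genes. ROSI gave 0 at days 3, 10 and 14 (1260, 1550 and 340 unadjusted), TBT against ROSI 517, 694 and 12 at days 3, 7 and 10, and the change of the TBT effect 413. These groups mix treatments or days by construction. They also hold AA and AO, which differ in 12694 genes, as 1 group, and AET within TBT day 14. That can add to the spread estimated over all groups, so the losses cannot be set down to the contradicted labels alone. At day 3 no treatments were mixed, as only DMSO day 7 replicate 1 joined DMSO. Of the named gene results 133 were the same, 99 lost and 29 reversed. Of the list results 512 were the same, 52 lost, 11 gained and 19 reversed, meaning that the direction of the list test turned, while some medians keep their sign. At day 10 with TBT these medians were PPAR targets 0.001, LXR targets -0.007, retinoic acid targets 0.055, lipogenesis -0.111, cholesterol synthesis 0.005, oxidative stress -0.062, glucocorticoid response 0.056 and chondrocyte 0.02. The genes were ABCA1 -0.007, ACACA -0.12, ADIPOQ 0.042, CCL2 -0.014, DHCR7 -0.27, FABP3 -0.67, FABP4 0.01, FADS1 -0.05, FADS2 -0.16, INSIG1 -0.14, MVD -0.12, PLIN1 -0.15, PLIN4 -0.26, PPARG -0.007, RRM2 0.008, SCD -0.095, SREBF1 -0.15, TAGLN -0.39, TUBA4A -0.25 and VIM 0.032, with DKK1 0.81 and HAPLN1 -0.084. In TBT against ROSI at day 10 they were focal adhesion and integrin -0.008 and heat shock -0.038, and with ROSI the collagen median was -0.032 at day 3 and 0.066 for the change of the ROSI effect. At day 10 the medians were early adipogenic regulators 0.059, oxidative phosphorylation 0.056, actin cytoskeleton 0.106, tubulin and microtubule 0.083, heat shock 0.089 and glucocorticoid response 0.346, and the genes ACVR1C -0.51, AQP7 -0.80, CRISPLD2 0.71, DKK1 2.08, ID3 0.51 and PNPLA2 0.061. The cholesterol synthesis median of DMSO day 10 against day 0 was 0.266, and the change of the TBT effect on ADIPOQ 0.11.

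With AO alone as day 0, COL1A1 at day 14 was 0.16 and TAGLN at day 3 0.053, and with AA alone SCD at day 14 was 0.16; the AA and AO levels differ. Of the list results, 113 were the same, 15 lost and 4 gained with AA alone, and 102, 16 and 14 with AO alone. With an estimated correlation 464 of the list results were the same and 196 lost.

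Leaving out each library in turn gave these counts of genes: TBT 1138 to 1546, 4583 to 5314, 4047 to 5604 and 4951 to 6694 at days 3, 7, 10 and 14; ROSI 5 to 74, 0 to 0 (620 to 1759 unadjusted), 18 to 2519 and 2 to 56; TBT against ROSI 2603 to 3948, 4405 to 4916, 3431 to 4921 and 5110 to 7125. DMSO against day 0 gave 10917 to 12078, 12573 to 13031, 11849 to 12755 and 12340 to 13443, AET against TBT day 14 492 to 5099, AA against AO 11618 to 12039, and the changes of the TBT and ROSI effects 1552 to 3015 and 0 to 3 (865 to 2594 unadjusted where 0). The MKI67 change of the TBT effect ran from -0.50, without TBT day 14 replicate 3, to 2.03, without TBT day 14 replicate 1. Where a group kept 1 library, it is assumed to vary like the other groups. Of the list results, 4980 were the same, 126 lost and 107 gained, and the median of proliferation genes in TBT against ROSI at day 14 (0.739) ran from -0.138, without TBT replicate 3, to 0.83, without TBT replicate 1 or 2. A fit on first runs alone was not run. At 37.3 to 205.4 M reads a library, depth limits genes near the floor, such as FABP4 at day 3, at 0.593 CPM with DMSO, and CEBPA, at 1.13.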

Other observations

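The test of less advanced differentiation was chosen after the principal components were seen and before its own result was.

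Genes outside the lipid and cytoskeletal groups also moved with TBT. The Wnt antagonist SFRP4 rose by 3.71 ± 0.28 at day 3, from 2.37 ± 0.398 to 31.6 ± 2.03 CPM, and the Wnt inhibitor DKK1 changed by -1.81, -2.08 and -2.74 at days 3, 7 and 10 (-1.53 at day 10 without DMSO replicate 2). The nerve growth factor receptor NGFR changed by 4.26, 4.27 and 5.29 from day 7, and the metalloproteinase inhibitor TIMP1 by 0.94, 0.94 and 2.02. The sialomucin gene EMCN, of the endothelial list, changed by 1.92, 2.72 and 1.64 at days 7, 10 and 14 (3.86 at day 10 without DMSO replicate 2), and the alkaline phosphatase gene ALPL, of the osteoblast list, by -0.72, -0.57, -1.27 and -1.23 at days 3, 7, 10 and 14 (adjusted p = 0.051 at day 3 on the most common flow cell alone). The hyaluronan link gene HAPLN1 changed by 0.83, 0.69, 1.14 and 0.76. The endothelial list gave adjusted estimated-correlation p values of 0.699, 0.167, 0.614 and 0.175 and the osteoblast list 0.277, 0.477, 0.222 and 0.166. TERT, the transgene of the line, was at -0.44 ± 0.09 at day 10 and -0.58 ± 0.10 at day 14 with TBT.

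TBT libraries of day 14 lay at lower values of the first principal component than DMSO libraries, -13.6 (replicate 3) to 20.8 against 40.7 to 50.6, toward the day 0 libraries. A hypothesis is less advanced differentiation with TBT. Of 1445 genes at least 4-fold higher in DMSO at day 10 than at day 0, 68.7% were lower with TBT at day 14, and of 982 genes at least 4-fold lower, 67.8% were higher, against 54% of the other genes lower. By the test, 320 genes of the first set were lower and 121 higher, and 280 of the second were higher and 24 lower. Without TBT replicate 3 the shares were 66.3% and 58.8%, the second below the 60% set beforehand. These shares were partly built in, as the first component parts day 0 from DMSO, and do not decide. PPARG (1.3 in DMSO at day 14 against day 0, and 0.59 with TBT against DMSO), ANGPTL4 (2.79 and 2.35) and PLIN2 (1.94 and 2.16) rose in differentiation and further with TBT, which the hypothesis does not give. Genes are not independent replicates, and a difference in the share of undifferentiated cells was not tested.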
